A study of Homo sapiens with 4 samples.

How the data were processed

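PML, the protein that organises PML nuclear bodies, was immunoprecipitated from cross-linked MDA-MB-231 cells, an established human triple-negative breast cancer line, and the bound DNA was sequenced. The labels name 2 PML ChIP libraries and 2 input libraries, and per the labels the duplicates were merged before peak calling. The libraries were made with a NEBNext Ultra II kit and sequenced as paired-end reads, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, BWA 0.7.12, Picard 2.0.1, MACS2 2.1.1.20160309 and HOMER 4.11.1 with the hg38 build; they list the tools without their settings, so the threshold behind the peak list is not given in the sources used here.

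The deposited data are 1 peak table annotated with HOMER column headings. Per the file headers, each peak has a start and an end, a score, the distance to the nearest TSS, an annotation class, a detailed annotation that names repeats and CpG islands, and the nearest gene. The peak score is a whole number given by the authors, with a scale that the file headers do not state, and it was used here only to rank and describe peaks within this list. The distances and positions are in bp as deposited. Because the table keeps no replicate apart, no value has a replicate error. Read depth per sample is unknown from the table, and enrichment over input could not be recomputed. All tests ran across genes or peaks of 1 merged list, which are not replicates, and all intervals cover counting error only.

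A gene had a promoter peak when the table named it as the nearest gene of a peak centred within 1000 bp of a TSS. The background was the 13948 protein-coding genes named anywhere in the table. This was the fallback fixed before the data were examined for the case that no genome annotation with transcripts was used. It has a cost: a gene enters the background only if some peak lies nearest to it, so shares are higher than among all genes. The table also gives each peak to 1 gene, so a peak shared by a bidirectional promoter counts for 1 partner. All shares were therefore also computed among 20033 RefSeq protein-coding genes of GRCh38.p14, an alternative chosen after seeing the data. Of the 13948 genes, 13931 were found in that RefSeq table by gene ID. The TSS position implied by peak centre and distance fell within 2 bp of an end of the named RefSeq gene for 28806 of 49084 peaks (58.7%), and RefSeq coordinates were used on that ground; the rest were not tested against transcript starts.

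24 gene lists were fixed before the data were examined, 21 spelled out and 3 defined by symbol pattern, with 2001 genes matched for 2002 entries, since 1 entry was an older symbol of another. Each list was compared with all other genes of the background by a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Shares have exact Clopper-Pearson 95% intervals. Cytosolic ribosomal protein genes were also compared with 4 pooled housekeeping lists (oxidative phosphorylation, proteasome, core spliceosome and aminoacyl-tRNA synthetases). The median of the highest promoter peak score of a list was placed among 10000 random lists of the same size. Matched random lists, 10000 per test, drew each member's substitute from the 200 genes nearest in length or the 40 nearest on the same chromosome. Chromosomes were divided into 10 Mb bins, and bins with 30 or more protein-coding genes were used for correlations with 100000 permutations. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

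The list test was tested on simulated data for the 13948 genes in 200 runs. Lists given 3-fold higher odds of a peak were called in 35% of cases, lists given 3-fold lower odds in 72.1%, and unchanged lists in 0.969%. A list that was not called can therefore still differ, most of all upwards. In these runs all unchanged genes had the same odds of a peak and were drawn independently. The 0.969% need not hold for real lists, because real shares vary with region and gene length. Length-matched lists, tested on simulated peaks that depended on gene length only, gave p under 0.05 in 5.42% of 240 tests, against 22.1% for the Fisher test.

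The named genes follow a rule fixed before the data were examined: the 10 protein-coding genes with the highest-scoring promoter peak, the 6 ribosomal protein genes with the highest-scoring promoter peak and up to 10 without one, the 3 highest of each other list with members lacking a peak where at most 5 do, and a fixed set of PML, mTOR, RONIN and senescence genes. Members of lists given only as counts are left out, and some genes that the rule names are not reported here. Motif searches, matching on GC content and CpG ratio, within-chromosome shuffles and overlap with transcript TSS windows had been planned where a genome was used, and were not run because none was used here. Alternatives covered the promoter window, the peaks kept, the gene assignment, the chromosomes and the background.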

Results

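PML ChIP-seq in MDA-MB-231 cells gave 1 merged peak list from 2 PML ChIP and 2 input libraries. The title of the series concerns ribosomal gene expression and senescence under a complex of PML, the kinase mTOR and RONIN (THAP11), a zinc-finger protein that binds promoters. The list gives where the authors called PML peaks in these cells, and enrichment over input could not be checked here. The deposited table holds no expression and no second condition, and it has no replicate error because the duplicates were merged by the authors. Coordinates are hg38.

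PML peaks lay mostly away from promoters, and the share near a TSS was higher among higher-scoring peaks. The list held 68937 peaks that do not overlap one another, with a median width of 436 bp and a median score of 34. Of these, 13770 (19.97%, exact 95% interval 19.7 to 20.3%) were centred within 1000 bp of a TSS, and 40022 (58.1%) lay over 10000 bp from one. The share of the genome at these distances was not computed, so neither an excess nor a lack of peaks at promoters can be read from them. Introns held 27304 peaks, intergenic DNA 24082 and the promoter class 7785. The share within 1000 bp was 45.2% in the highest-scoring quartile of peaks, and 16.6%, 10.7% and 7.39% in the next 3. Peaks near a TSS were also wider, with a median of 739 bp against 392 bp for peaks over 10000 bp away. Among the 5000 highest-scoring peaks the share within 1000 bp was 72.6%.

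**Figure D1:**
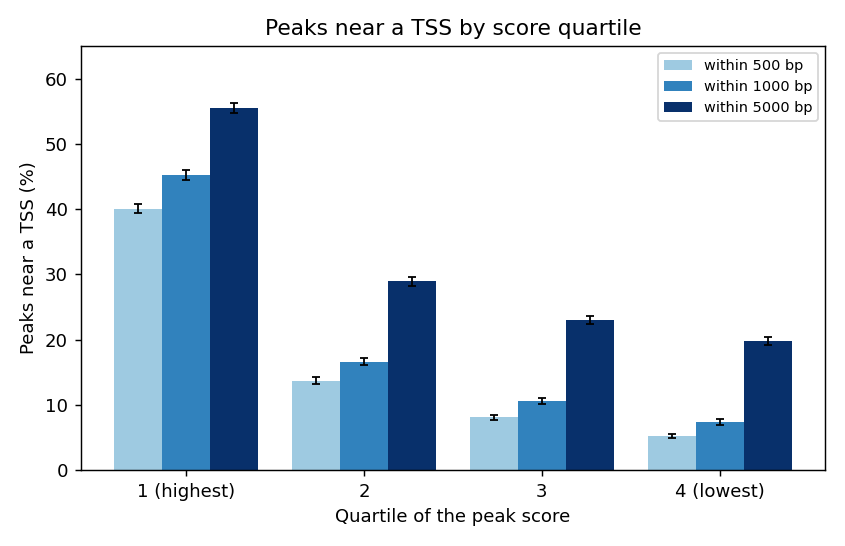
Share of PML peaks centred within 500, 1000 or 5000 bp of a TSS (vertical axis, percent) in each quartile of the peak score (horizontal axis); bars are shares and error bars exact 95% intervals. The share within 1000 bp went from 45.2% in the highest quartile to 7.39% in the lowest.

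The 10 protein-coding genes with the highest-scoring promoter peak were LRP6, TMEM222, CPSF1, MAF1, C1QTNF3, ZNF341, TRIM41, POLR2J3, ZNF696 and VPS28. LRP6, a Wnt co-receptor, led with a peak on chromosome 12 from 12265964 to 12267599, in the 5' UTR, with a score of 899. CPSF1, a subunit of the mRNA cleavage and polyadenylation factor, had a score of 811, and MAF1, a repressor of RNA polymerase III, had 750. The peaks of CPSF1, MAF1, ZNF696 and VPS28 all lie on chromosome 8 between 143290499 and 144431213. The 10 Mb bin around them held 864 peaks over 10000 bp from a TSS, against a median of 90 over 241 bins. The peaks with the highest scores of all were not at protein-coding promoters. The highest, with a score of 5641, was intergenic on chromosome 1 from 125179991 to 125180363, and a peak at the U2 small nuclear RNA gene RNU2-1 had a score of 2304. Both were picked out after their scores were seen. The highest lay 3661065 bp from the nearest TSS, and 7 of the 15 highest-scoring peaks were intergenic. Whether reads of repeated sequence gave such scores was not tested, so they do not show where PML binds most.

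Genes of cytosolic ribosomal proteins had a PML peak at the promoter more often than other genes. Of the 57 named in the table, 54 had one (94.7%, interval 85.4 to 98.9%), against 78.5% of other genes (two-sided Fisher exact test, adjusted exact p = 0.0101). High scores were 417 at RPS7, 298 at RPL37, 243 at RPS21, 230 at RPS3A and 209 at RACK1. The RPS7 peak lay on chromosome 2 from 3574884 to 3576259, in an intron 311 bp from the TSS, and the RPL37 peak on chromosome 5 from 40834938 to 40836194. Another 23 of the 80 ribosomal protein genes were the nearest gene of no peak. RPL11, RPL12, RPL13A, RPL18, RPL19, RPL23, RPL23A, RPL30 and RPL34 were among those without a promoter peak by this assignment. When the annotation column was also used, 59 of 61 ribosomal protein genes had a promoter peak. A peak lay at either gene end for 66 of 80. Some genes without an assigned promoter peak may therefore have one. Among all RefSeq protein-coding genes the share was 54 of 80 (67.5%, interval 56.1 to 77.6%) against 54.4% (adjusted exact p = 0.0413), a background chosen after seeing the data. Against neighbouring RefSeq genes the list did not pass (8.41 points, adjusted permutation p = 0.224), nor with a 5000 bp window (adjusted exact p = 0.0981) or the 5000 highest-scoring peaks (adjusted exact p = 0.142).

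The ribosomal protein promoters were not separated from other housekeeping promoters by the test. In the 4 pooled lists of oxidative phosphorylation, proteasome, spliceosome and aminoacyl-tRNA synthetase genes, 134 of 152 promoters (88.2%) had a peak, 6.58 percentage points below the ribosomal protein genes (two-sided Fisher exact test, p = 0.202). Among all RefSeq genes the difference was 3.99 points (exact p = 0.584), and with the 5000 highest-scoring peaks 13.4 points (exact p = 0.052). The median of the highest promoter score over ribosomal protein genes was 68, against 63 over all genes with a promoter peak, at percentile 70.1 of 10000 random lists. Set among the pooled housekeeping genes with a peak, whose median was 58, it stood at percentile 96.8. With only the higher-scoring part of the peaks (34468 peaks), the ribosomal protein genes did not pass the test against all other genes (9.47 points, adjusted exact p = 0.234).

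Of 38 translation initiation and elongation factor genes, 36 (94.7%) had a promoter peak (adjusted exact p = 0.0296), led by EIF5B, which joins the ribosomal subunits, with a score of 206. Aminoacyl-tRNA synthetases had a peak at 26 of 27 promoters (96.3%, adjusted exact p = 0.0495), TARS2 with the highest score, 150. The factors did not pass with the higher-scoring part of the peaks (adjusted exact p = 0.081) or without the low-expression lists (adjusted exact p = 0.055), but did among all RefSeq genes (80%, adjusted exact p = 0.00158). The synthetases did not pass with either of these (adjusted exact p = 0.407 and 0.0878), nor among all RefSeq genes (26 of 39, 66.7%, adjusted exact p = 0.197). Mitochondrial ribosomal proteins (47 of 54, adjusted exact p = 0.219) and ribosome biogenesis and RNA polymerase I genes (41 of 47, adjusted exact p = 0.297) did not pass the test in the main comparison. The first passed with a 500 bp window (adjusted exact p = 0.0174), and the second with the annotation column (adjusted exact p = 0.0318) and either gene end (adjusted exact p = 0.0099). Neither passed among all RefSeq genes, which add 24 and 21 members that the table does not name. There 47 of 78 (60.3%, adjusted exact p = 0.435) and 41 of 68 (60.3%, adjusted exact p = 0.45) had a peak, against 54.45% of other genes. Against neighbouring RefSeq genes the differences were 1.59 and 1.16 points. With the 5000 bp window they were 0.0714 and 6.67 points, and neither list passed. Their median scores were 82 and 86, at percentiles 95.4 and 97.7 of random lists, not adjusted over the 24 lists. MRPL40 (260) and MRPS26 (226) led the first, and DKC1 (219), the dyskerin pseudouridine synthase, and NOP56 (209), a box C/D snoRNP protein, led the second.

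**Figure D2:**
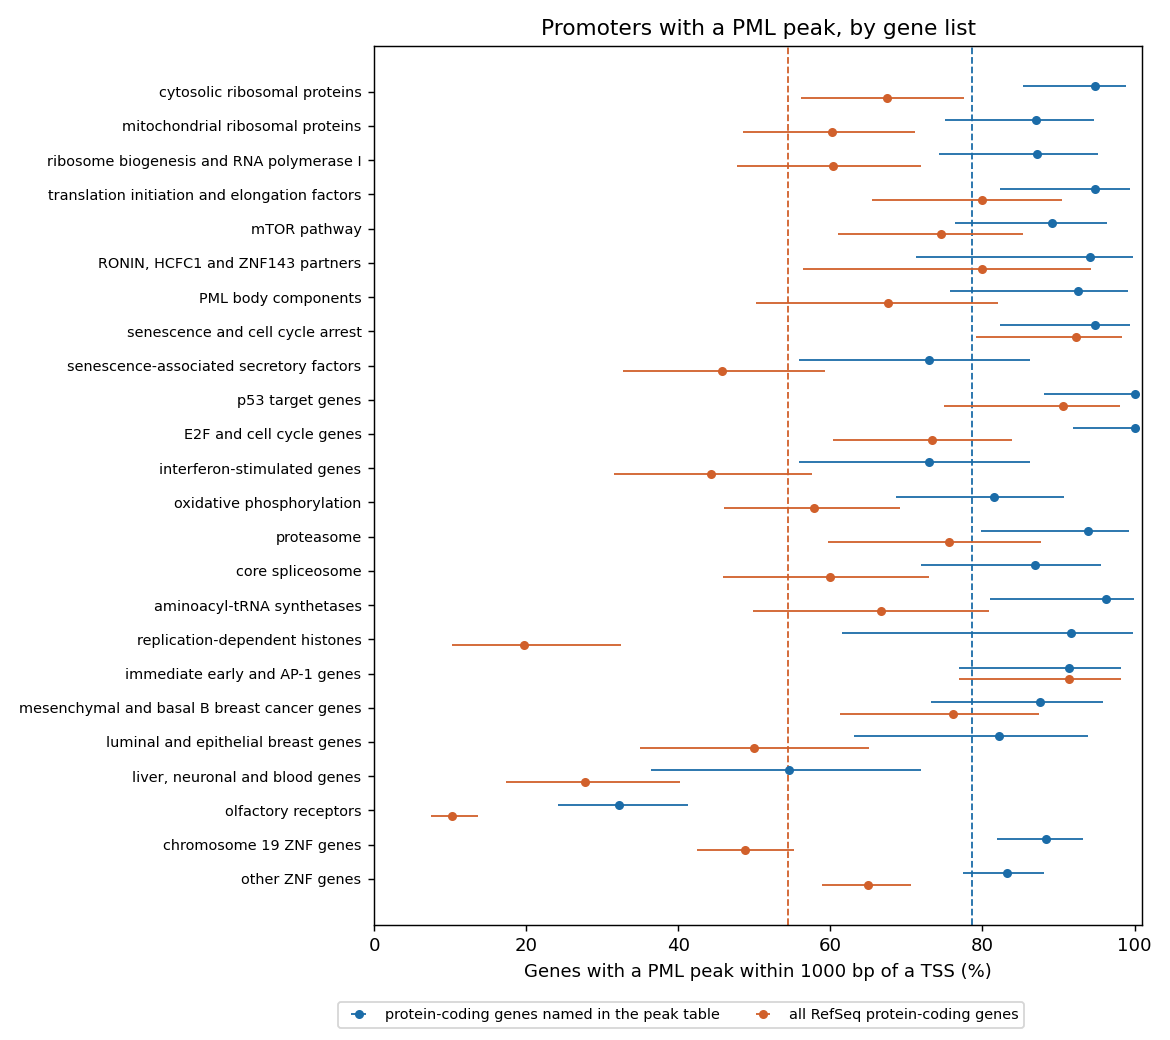
Share of genes with a PML peak within 1000 bp of a TSS (horizontal axis, percent) for 24 gene lists (vertical axis), among protein-coding genes named in the peak table (blue) and among all RefSeq protein-coding genes (orange); bars are exact 95% intervals and dashed lines the shares over all genes, 78.6% and 54.5%. Cytosolic ribosomal protein genes stood at 94.7% and 67.5%, and olfactory receptors at 32.3% and 10.3%.

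Cell cycle and arrest genes had PML peaks at nearly all promoters named in the table. All 44 E2F and cell cycle genes had one (adjusted exact p = 0.000602), among them MCM4 (score 220), a subunit of the replicative helicase, and RRM2 (192), a ribonucleotide reductase subunit. All 29 p53 target genes had one (adjusted exact p = 0.0101), among them SESN1 (358), the DNA repair gene XPC (188) and GADD45A (187). Of 38 senescence and cell cycle arrest genes, 36 had one (adjusted exact p = 0.0296), with FOXO3 at 292, BHLHE40 at 275 and HMGB1 at 239. Secretory factors of senescent cells did not stand apart (27 of 37, adjusted exact p = 0.482): the urokinase gene PLAU had a score of 199, and IL6 and CXCL8 were the nearest gene of no peak. Interferon-stimulated genes had 27 of 37 (adjusted exact p = 0.482), and were called less often with either gene end (adjusted exact p = 0.0282). Among all RefSeq genes, 92.3% of senescence and arrest genes had a promoter peak against 54.4% (adjusted exact p = 2.95e-06), and 44 of 60 E2F and cell cycle genes (73.3%, adjusted exact p = 0.00855). The senescence and arrest list did not pass with a 500 bp window (adjusted exact p = 0.234) or against neighbouring genes (adjusted permutation p = 0.0642). With the 5000 highest-scoring peaks the E2F difference was -5.18 points (adjusted exact p = 0.592) and that of p53 targets 4.25 points (adjusted exact p = 0.754). Neither list passed with a 5000 bp window (adjusted exact p = 0.0585 and 0.0981).

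Single senescence regulators varied in score. RB1, the retinoblastoma protein gene, had a promoter peak with a score of 202 on chromosome 13 from 48303359 to 48304597. The p21 gene CDKN1A had 75, CDKN2A 55 and CDKN2B 42. MDA-MB-231 is known for a homozygous deletion at CDKN2A and CDKN2B, so what gave their peaks is open. Both count among the senescence and arrest genes with a promoter peak. HIRA and HMGA2 had no promoter peak assigned.

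The mTOR pathway and RONIN lists did not pass the test in the main comparison. Of 46 mTOR pathway genes, 41 (89.1%) had a promoter peak (adjusted exact p = 0.182). RICTOR, the scaffold of mTOR complex 2, had a score of 450 on chromosome 5 from 39073515 to 39075322, followed by SESN1 (358) and MIOS (235). RPTOR had 130, EIF4EBP1 61 and RPS6KB1 26. Of 17 genes of RONIN and its partners, 16 (94.1%) had one (adjusted exact p = 0.219): KMT2A had a score of 345, ZNF143 175, GABPA 130, HCFC1 112 and THAP11, which encodes RONIN, 55. Among all RefSeq genes both lists passed the test, with 74.5% (adjusted exact p = 0.00694) and 80% (adjusted exact p = 0.0413), but neither did against neighbouring RefSeq genes (adjusted permutation p = 0.0807 and 0.127). Of 27 genes of PML bodies, 25 had a peak (adjusted exact p = 0.182). Among all RefSeq genes this was 25 of 37 (67.6% against 54.4%, adjusted exact p = 0.193). The median score of these 25 genes was 75, against 63 over all genes with a promoter peak, at percentile 80.9 of random lists. DAXX (48) and SP100 (13) lay below that median, and 13 is the lowest score of the whole peak list. No peak overlapped the PML gene itself, and ATRX was the nearest gene of none.

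MTOR had no promoter peak but some of the strongest peaks inside the gene. The peak on chromosome 1 from 11247626 to 11248096, over exon 7, had a score of 1192 and rank 8 of the list. Others lay from 11237844 to 11238619 in intron 12 (score 687), from 11230926 to 11231437 in intron 17 (221) and from 11212313 to 11212910 in intron 22 (260). Among gene body peaks over 10000 bp from a TSS with a score of 200 or more, which 18 genes had, MTOR held 4 and no other gene more than 2. The cut of 200 was not planned and lies just below the lowest of these 4 MTOR scores, 221. What gave these peaks stays open, as set out under the other observations.

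**Figure D3:**
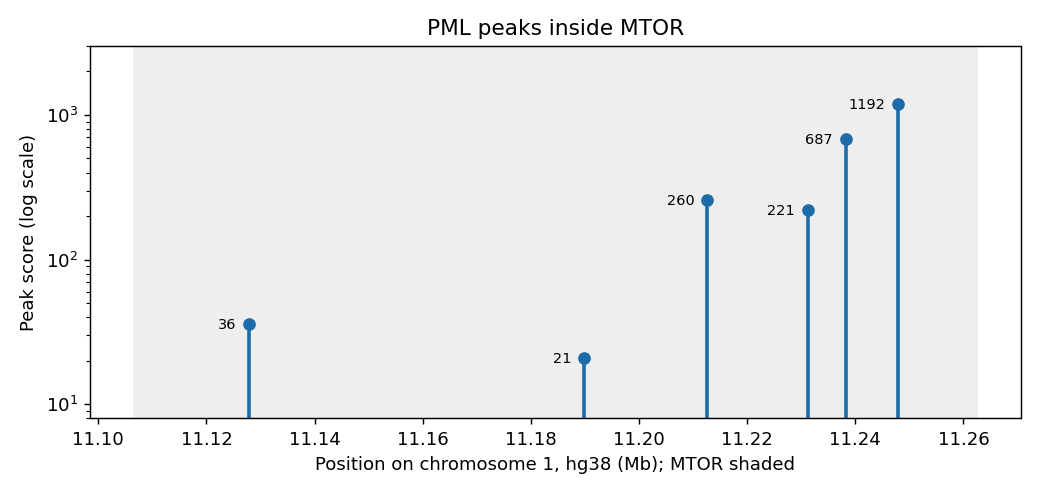
Score of each PML peak (vertical axis, log scale) by its position on chromosome 1 in hg38 (horizontal axis, Mb) across the MTOR gene (shaded); points are peaks of the merged list. The highest has a score of 1192, and exon numbers of MTOR increase from right to left.

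Genes of other tissues had PML peaks at the promoter less often than other genes. Olfactory receptors had a promoter peak at 40 of 124 genes (32.3%, adjusted exact p = 3.21e-27), and liver, neuronal and blood genes at 18 of 33 (54.5%, adjusted exact p = 0.0101), the latter lost with a 5000 bp window (-2.12 points, adjusted exact p = 0.785). Immediate early and AP-1 genes had 32 of 35 (91.4%, adjusted exact p = 0.141) and the highest median score of the 24 lists, 105, at percentile 99.8 of random lists. The phosphatase gene DUSP1 had 353 and FOSL1, an AP-1 subunit, 293. The list passed among all RefSeq genes (91.4% against 54.4%, adjusted exact p = 2.06e-05) and with the higher-scoring part of the peaks (adjusted exact p = 0.0161). Mesenchymal and basal B genes had 35 of 40 (adjusted exact p = 0.326) with a median score of 84, and luminal and epithelial genes 23 of 28 (adjusted exact p = 0.819) with 37, at percentiles 96.2 and 0.395. With either gene end the luminal list was called less often (20 of 46, adjusted exact p = 0.0125). ITGA2, an integrin subunit, had 216 and EPCAM, an epithelial adhesion gene, 142. Chromosome 19 ZNF genes had 122 of 138 (adjusted exact p = 0.0135), but 48.8% against 54.5% among all RefSeq genes (adjusted exact p = 0.118). With either gene end they were called less often (-15.2 points, adjusted exact p = 7.14e-06), and they did not pass with a 5000 bp window or the higher-scoring part (adjusted exact p = 0.351 and 0.447). Other ZNF genes had 174 of 209 (adjusted exact p = 0.182). Replication-dependent histone genes had 11 of 12 in the table (adjusted exact p = 0.525), but 11 of 56 (19.6%) among all RefSeq genes (adjusted exact p = 1.37e-06) and 1.78 points above RefSeq genes of similar length (adjusted permutation p = 0.842), so their direction depends on the background, as does that of the luminal list. The proteasome (31 of 33, adjusted exact p = 0.076), spliceosome (33 of 38, adjusted exact p = 0.404) and oxidative phosphorylation lists (44 of 54, adjusted exact p = 0.772) did not pass. Among all RefSeq genes the proteasome (75.6%, adjusted exact p = 0.0141), mesenchymal (76.1%, adjusted exact p = 0.00694) and other ZNF lists (64.9%, adjusted exact p = 0.00158) did, as did oxidative phosphorylation with either gene end (58 of 76, adjusted exact p = 0.0282).

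Repeat elements were named for part of the list. LTR elements were named for 6458 peaks (9.37%), LINEs for 5796 (8.41%), SINEs for 2494 (3.62%), SVA retroposons for 697 (1.01%), simple repeats for 629 (0.912%) and satellites for 224 (0.325%). CpG islands were named for 4598 (6.67%), and rRNA or tRNA repeats for 4 and 2. LTR, LINE and SINE peaks made up 7.50%, 6.10% and 2.26% of the higher-scoring part of the list, and CpG islands 9.81%.

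Promoter peaks were unevenly spread along the chromosomes. Over 241 bins of 10 Mb, the share of RefSeq protein-coding genes with a promoter peak ran from 12.5% to 87.3%, with a median of 56.4%. The lowest lay on chromosome 19 from 20 to 30 Mb, and the highest on chromosome 5 from 170 to 180 Mb. The share went with the number of distal peaks in a bin, with Pearson r 0.48 and Spearman rho 0.59 (permutation p = 1e-05 for both, the smallest they can give). Without the 2 bins farthest from the median, r was 0.52. With the number of genes in a bin, r was -0.11 (permutation p = 0.0768) and rho -0.09 (permutation p = 0.15). Over the 4 coefficients the Benjamini-Hochberg adjusted p was 2e-05 for distal peaks and 0.102 and 0.15 for genes; bins are not independent replicates, and these tests were chosen after seeing the data.

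**Figure D4:**
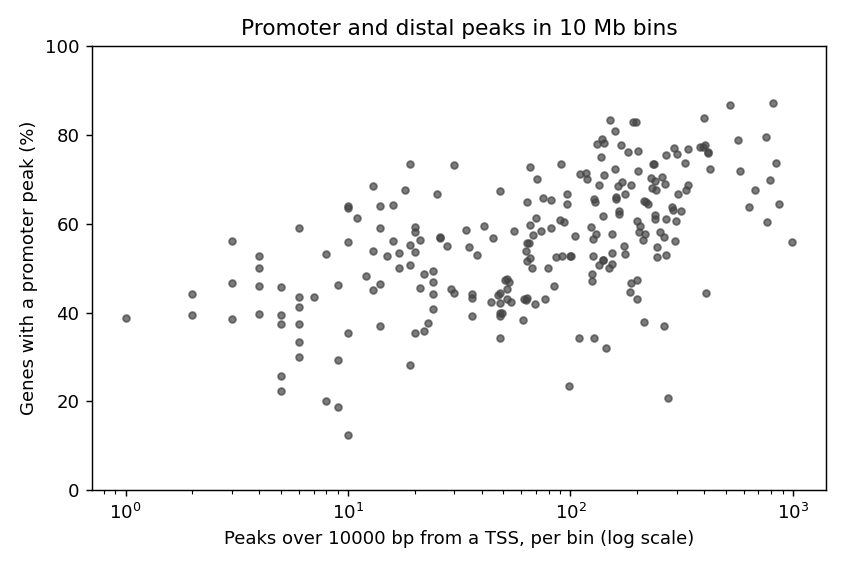
Share of protein-coding genes with a promoter peak (vertical axis, percent) against the number of peaks over 10000 bp from a TSS (horizontal axis, log scale); each point is a 10 Mb bin with 30 or more genes. The share ran from 12.5% to 87.3%, with Spearman rho 0.59.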

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

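Differences below are list minus other genes in percentage points, with the adjusted p of the Fisher exact test or of random lists where a call changed; the cause of a change was not tested unless stated. Alternatives that use all RefSeq protein-coding genes, either gene end, the annotation column, similar length or neighbouring genes were chosen after seeing the data. The ribosomal protein list kept its direction under all 13 alternatives (8.41 to 24.3 points). It lost its call with the 5000 bp window (9.56, exact p = 0.0981), the higher-scoring part of the peaks (9.47, p = 0.234), the 5000 highest-scoring peaks (11.8, p = 0.142) and neighbouring genes from all RefSeq genes (8.41, p = 0.224). Against housekeeping promoters it turned to -1.97 points with the higher-scoring part (exact p = 0.858), and rose to 9.21 with the 500 bp window (p = 0.0924) and 13.4 with the 5000 highest-scoring peaks (p = 0.052); no alternative gave a p under 0.05. Its score percentile was 54.0 for summed peaks and 96.8 among housekeeping genes. The senescence and arrest list kept its direction throughout but lost its call with the 500 bp window (11.03, exact p = 0.234), the 5000 bp window (13.1, p = 0.0585), the 5000 highest-scoring peaks (13.5, p = 0.148), a background without low-expression lists (15.7, p = 0.055), the annotation column (14.4, p = 0.0516) and neighbouring genes (14.6, p = 0.0642). The mTOR list gained a call with the 500 bp window (16.4, exact p = 0.031), all RefSeq genes (20.1, p = 0.00694), either gene end (23.9, p = 0.000344) and similar length from all RefSeq genes (16.1, p = 0.04), and the RONIN list with the last 3 of these (25.6, 36.6 and 26.1, p = 0.0413, 0.000539 and 0.0414). Neither passed with neighbouring RefSeq genes (13.9 and 22.3, permutation p = 0.0807 and 0.127). The secretory factors passed no alternative. For the other lists p alone is given, exact or, for similar length and neighbours, by permutation, where not given above with the list. The translation factors also lost their call with the 5000 bp window (0.161), the 5000 highest-scoring peaks (0.765) and neighbours (0.0642). The synthetases lost theirs with these (0.493, 0.592 and 0.0651), similar length (0.0698) and, from RefSeq genes, similar length (0.401) and neighbours (0.213). Liver, neuronal and blood genes lost theirs with the 5000 highest-scoring peaks (0.148). Chromosome 19 ZNF genes lost theirs with these peaks (0.102) and RefSeq genes of similar length (0.0679) or nearby (0.309). Either gene end called histone genes less often (7.02e-06), and immediate early (0.000189), other ZNF (0.00425), proteasome and mesenchymal genes (0.0282 each) more often. The proteasome also gained a call with the 500 bp window (0.0174), the annotation column (0.0266) and RefSeq genes of similar length (0.0181). Immediate early genes gained one with the 5000 highest-scoring peaks (0.000877) and similar length (0.04). With RefSeq genes of similar length and nearby, immediate early (0.0008 and 0.00096), mesenchymal (0.0223 and 0.0459) and other ZNF genes (0.0132 and 0.00096) gained theirs.

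Of 24 lists, 7 had promoter peaks more often and 2 less often. The first count was 0 with the 5000 bp window, 4 with the higher-scoring part, 1 with the 5000 highest-scoring peaks, 4 without low-expression lists, 11 with all RefSeq genes, 14 with either gene end, 4 with neighbouring genes and 11 with similar length from all RefSeq genes. The second was 1 with the 5000 bp window, 1 with the 5000 highest-scoring peaks, 0 without low-expression lists, which removes both lists by construction, and 6 with either gene end. The share of peaks near a TSS was 16.8% at 500 bp, 31.8% at 5000 bp, 30.9% in the higher-scoring part, 72.6% in the 5000 highest-scoring peaks and 11.3% by annotation class. In the higher-scoring part LTRs took 7.50%, LINEs 6.10%, SINEs 2.26%, retroposons 1.10% and CpG islands 9.81%.

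Some lists changed sign. With the 5000 highest-scoring peaks these were E2F (-5.18), oxidative phosphorylation (-6.70), proteasome (-11.2), histone (-6.68), luminal (-19.8) and chromosome 19 ZNF genes (-8.21). Histone genes gave -30.9 with the higher-scoring part, -34.9 with all RefSeq genes, -33.2 with either gene end and -4.68 with neighbouring RefSeq genes. Luminal genes gave -2.72 with the 500 bp window, -3.55 with the higher-scoring part, -4.48 with all RefSeq genes, -20.0 with either gene end, -4.23 with similar length and -4.15 with neighbours from all RefSeq genes. Chromosome 19 ZNF genes gave -5.74, -15.2 and -6.58 with all RefSeq genes, either gene end and similar length. Oxidative phosphorylation gave -0.167 with neighbouring RefSeq genes.

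No paired analysis was possible because the authors merged the duplicates before peak calling, nor was leaving out a replicate. Motif alternatives, the 5' gene end alone and centre against overlap were not run. Read depth is unknown, so peaks that depth hid cannot be counted.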

Other observations

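LTR12C, an endogenous retroviral promoter element, was the repeat family with the most PML peaks. It was named for 970 peaks, 5.67% of the 17097 peaks named as a repeat, and 58.9% of these were in the higher-scoring part of the list, against 38.5% of repeat peaks (two-sided Fisher exact test, adjusted p = 6.41e-38 over 75 families). LTR12D (55 peaks, 74.5%), MER52A (384, 50.5%), SVA_B (125, 62.4%) and SVA_D (313, 51.8%) also stood higher than repeat peaks, among 8 families in all, and 12 stood lower, such as AluSz (22.5%). The higher-scoring part holds 34468 of all 68937 peaks, so MER52A and SVA_D stood near the share over the whole list. How often each family occurs in the genome was not used here, and these tests were chosen after seeing the data.

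Among 103 families of symbols that share a prefix, each with 20 or more genes, 14 had promoter peaks more often than other RefSeq protein-coding genes and 21 less often, in tests chosen after seeing the data. Against neighbouring genes some calls were lost, such as RNF, RAB, DNAJC and TRIM (adjusted permutation p = 0.325, 0.199, 0.194 and 0.117). ZNF genes gained a call (adjusted permutation p = 0.00187), and the families with counts below kept theirs. UBE genes of ubiquitin conjugation had 36 of 42 (85.7%, adjusted p of the Fisher exact test 0.00024). Keratin (KRT) genes had 6 of 55 (10.9%), beta-defensin (DEFB) genes 3 of 39 and chemokine (CCL) genes 1 of 28. PRAMEF genes had 0 of 23; they have near-identical copies, among which reads cannot be placed with certainty. MDA-MB-231 is known for a homozygous deletion at CDKN2A and CDKN2B, yet the list holds promoter peaks there with scores of 55 and 42. What gave those peaks was not tested.

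Of the tests below, the housekeeping comparison with the 5000 highest-scoring peaks was planned, and the others were chosen after seeing the data. What the neighbouring-gene test of the ribosomal protein genes and the test of housekeeping promoters by bin should give was written before their values were seen. The higher share of ribosomal protein promoters with a peak was set against 4 explanations. A background limited to genes in the table is argued against by the difference of 13.1 points among all RefSeq genes (adjusted exact p = 0.0413), and gene length by 22.9 points against genes of similar length (permutation p = 0.0002, the smallest it can give); short length would lower their share, since 40.1% of genes in the shortest of 4 length groups had a peak and 66.9% in the longest. Location stays open: against neighbouring RefSeq genes the difference was 8.41 points (p = 0.14), and 14.9 points (p = 0.0028) against neighbours named in the table, both by random lists in a permutation test. The first value met what was written beforehand for location and was first read that way. That reading was changed afterwards because of the second value. The second covers only genes that are the nearest gene of some peak, so it cannot decide against location. What was written for location was therefore met by the first value, but a p that misses the threshold does not show that location is the cause. Ribosomal protein genes had a promoter peak at 9 of 18 (50%) in the bins poorest in distal peaks. In the richest bins 25 of 33 (75.8%) had one (two-sided Fisher exact test, p = 0.119). A property shared with other housekeeping promoters may account for the pattern, since the difference from these was 3.99 points (exact p = 0.584), although it was 13.4 (exact p = 0.052) with the 5000 highest-scoring peaks and a p that misses the threshold does not show equality.

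The strong peaks inside MTOR were set against 3 explanations. An MTOR coding sequence without introns, such as a plasmid, stays open: 0 peaks with a score of 100 or more lay from exon 23 on, but that cut was set just past the last of the 4. Of these, 3 were centred in introns, but exon limits were not used here, so they may span exons. Repeats stay open: 0 of the 4 peaks were named as one, but such names were also missing at other very strong peaks. Of the 7 intergenic peaks among the 15 highest-scoring of the list, 5 had neither a repeat nor a CpG island named. Short DNA of fixed ends, such as an amplified product, could not be told apart: the median width percentile among peaks of like score was 15.8, with 3.51 and 1.77 for the peaks of scores 260 and 221, and 28 and 75 for the 2 highest, which had only 25 and 4 peaks for comparison (scores 0.75 to 1.33 times, a range chosen after the widths were seen).

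The uneven share of promoters with a peak along chromosomes was set against 3 explanations, of which gene density is argued against by rho -0.09 (-0.0936). If silent genes were the cause, housekeeping promoters should have a peak as often where distal peaks are few, and if regional read depth such as DNA copy number were, less often. Of the 4 housekeeping lists, 70.1% had one in the bins richest in distal peaks and 58.2% in the poorest, a difference of 11.9 points (two-sided Fisher exact test, p = 0.153), so neither can be told apart at this number of genes. Olfactory receptors had a peak at 26 of 206 genes in the richest bins and 0 of 65 in the poorest (12.6 points, exact p = 0.00105), which counts against silent genes as the whole cause if these are silent throughout; their expression was not measured here, and they lie in clusters. A wider set of 482 genes that adds the ribosome and translation lists gave 20.01 points (exact p = 0.000312), which would favour regional depth; that set was not planned, was run first, and was replaced by the 4 lists fixed before the data were examined.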
